A study of Mus musculus with 18 samples.

How the data were processed

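The values used were raw counts per gene that the authors deposited, for 54838 Ensembl gene IDs in 18 libraries, with all sample columns used. Per the labels, cells of each organoid line were seeded singly in Matrigel, moved to 1% or 21% O2 after 48 h and kept there for another 48 h, and 2 to 3 wells were harvested. The processing notes name Trimmomatic 0.35 for trimming, STAR 2.7.0a for alignment to mm10, SAMtools 1.9, featureCounts of Subread 1.5.0 for counting and edgeR 3.24.3. The annotation release and the strand setting of the count were not given in the sources used here, so genes that overlap another gene on the opposite strand, and pseudogene copies, are uncertain. The library protocol names a stranded mRNA kit and also ribosomal depletion.

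Symbols and coordinates were taken from GENCODE M21 (mm10). Of the IDs, 54723 had a symbol, 102 shared a symbol with a gene of larger count and were kept under their ID, and 0.0481% of counts fell on IDs without a symbol. Coordinates run from gene start to gene end. The design, the gene lists, the tests and the alternatives were fixed in choices made before the data were examined, except for those stated below as chosen later.

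Genes were kept by the default filter of edgeR (filterByExpr) on the 4 groups, which left 19356. Libraries were scaled by TMM, with factors from 0.923 to 1.05. The model held 4 group means, fitted with the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, and 5 contrasts were tested two-sided: hypoxia in KPC, hypoxia in KPCS, their difference (interaction), and KPCS against KPC at each oxygen level. Benjamini-Hochberg adjustment was made over all tested genes per contrast, and genes with adjusted p under 0.05 were called. The SE of a log2 fold change was its absolute value over the square root of the F statistic. The common biological coefficient of variation was 49.7%, and 17.0% with the organoid line as a block.

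The 2 libraries of a line came from 1 animal. Their pairing was checked on log2 CPM after the group means were removed, over 12887 genes, and the correlation ranged from 0.296 in line KPC625 to 0.948. The fit without pairing was fixed in advance, and the fit with the line as a paired block was run as an alternative for the contrasts within lines. Counts of called genes are given from both for the lists that passed. Genotype is constant within a line, so a block cannot be used for the genotype contrasts.

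Of 27 gene lists written in advance, 26 had at least 3 tested members. They were glycolysis, HIF targets outside glycolysis, HIF pathway components, oxidative phosphorylation, the TCA cycle, S phase, mitosis, the unfolded protein and integrated stress response, cholesterol synthesis, interferon response, NF-kB, the U2 snRNP and spliceosome, ribosome biogenesis, ribosomal proteins, p53 targets, NRF2, invasion, duct epithelium, gastric and basal differentiation, markers of acinar, endocrine, fibroblast, leukocyte, endothelial and red or glial cells, and RNA quality signs. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 26 lists per contrast. Camera with a correlation estimated per list, and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. The response of a list per line was the mean over its genes of log2 CPM at 1% minus 21% O2, compared between genotypes with an exact permutation test, two-sided, over all splits of 9 lines into 5 and 4. Its smallest possible p is 0.0159.

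Genes were named by rule: the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, without predicted genes and clone names, and for hypoxia with the same direction in every line. Where fewer than 5 passed, the 5 smallest p were named. Up to 4 members of a described list with the smallest p and the members against its direction were added, and 11 genes were fixed in advance.

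The alternatives were the size factors of DESeq2, no filter, a stricter filter (1 CPM in 4 samples and a mean of 2 CPM), the Wald test of DESeq2 1.42.0, limma-voom with the line as a random effect (consensus correlation 0.697), a fit of only the 2 groups compared, the paired block and leaving out each line. For list responses they were a prior count of 0.5, the median over the list, and members with a mean of at least 10 CPM. After the values were seen, 3 alternatives were added: lines KPC251 and KPCS520 left out, lines KPC251, KPCS520 and KPC625 left out, and the paired block without line KPC625.

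Recovery was measured on simulated counts drawn from the mean and dispersion of each gene and the size of each library (for the block, from the mean of each line and the dispersion with the block), in which 100 genes were changed 2-fold and 100 were changed 4-fold in each contrast. The unpaired fit recovered 27% and 67% for hypoxia in KPC, 21% and 59% for hypoxia in KPCS, 11% and 45% for the interaction, 30% and 66% for genotype at normoxia, and 25% and 63% for genotype at hypoxia. With the block the figures were 60% and 83%, 54% and 86%, and 40% and 75% for the first 3. False calls made up 0 to 8.92% of calls.

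Splicing, allele-specific expression and variants could not be examined, since gene counts carry no reads. The counts hold no molecular identifiers, so precision is given only through the spread between libraries.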

Results

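RNA was sequenced from 9 mouse organoid lines grown from pancreatic duct cells, each line from a different animal. All lines carried KrasG12D and Trp53R172H, an activated oncogene and a mutated tumour suppressor (KPC), and 4 of them were labelled heterozygous for Sf3b1 (KPCS). Sf3b1 encodes a core subunit of the U2 snRNP, the particle that recognises the branch point during splicing. Each line was sampled after 48 h at 21% O2 (normoxia) and after 48 h at 1% O2 (hypoxia), which gave 5 KPC and 4 KPCS libraries at each oxygen level and 18 libraries in all. The labelled KPC lines were KPC251, KPC293, KPC305, KPC571 and KPC625, and the labelled KPCS lines were KPCS398, KPCS520, KPCS530 and KPCS677. The total per library, in M counts (megacounts), was 45.9 ± 7.42 M (mean ± SD, n = 5) in KPC normoxia, 43.8 ± 4.79 M (n = 5) in KPC hypoxia, 44.3 ± 8.42 M (n = 4) in KPCS normoxia and 42.0 ± 5.18 M (n = 4) in KPCS hypoxia. Totals ranged from 33.2 to 52.2 M. Values are TMM-scaled CPM (counts per M counts of the library) given as mean ± SD, and log2 fold changes are given ± SE from edgeR with adjusted p over 19356 tested genes. Coordinates are in mm10.

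Sf3b1 (ENSMUSG00000025982, chromosome 1, 54985169 to 55027481, minus strand) served as a measurement of the labelled genotype. In normoxia it stood at 244.7 CPM in the line labelled KPC251, 379.5 in KPC293, 357.1 in KPC305, 380.8 in KPC571 and 365.7 in KPC625. In the lines labelled KPCS it stood at 221.5 CPM in KPCS398, 367.5 in KPCS520, 235.1 in KPCS530 and 227.7 in KPCS677. The hypoxia libraries gave 233.9, 381.6, 383.5, 403.7 and 393.3 CPM for KPC251, KPC293, KPC305, KPC571 and KPC625, and 233.8, 404.8, 251.9 and 242.8 CPM for KPCS398, KPCS520, KPCS530 and KPCS677. The library labelled KPC251 thus lay at 66.0% of the mean of the other 4 KPC lines in normoxia and 59.9% in hypoxia, and at 107% and 96.3% of the mean of the other 3 KPCS lines. The line labelled KPCS520 lay at 161% and 167% of the other 3 KPCS lines, and at 99.1% and 104% of the 4 other KPC lines. Group means were 345.6 ± 57.3 CPM (n = 5) in KPC and 263.0 ± 69.9 (n = 4) in KPCS at normoxia, and 359.2 ± 70.6 and 283.3 ± 81.3 at hypoxia. The log2 fold change of KPCS against KPC was -0.39 ± 0.21 (edgeR adjusted p = 0.886) at normoxia and -0.34 ± 0.21 (adjusted p = 0.992) at hypoxia. With the lines labelled KPC251 and KPCS520 left out, a choice made on Sf3b1 itself and therefore circular for this gene, the values were -0.70 (adjusted p = 0.00926) and -0.68 (adjusted p = 0.0121). Samples were kept in their labelled groups throughout, so every direction drawn below from genotype rests on labels that Sf3b1 contradicts in 2 of 9 lines.

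**Figure D1:**
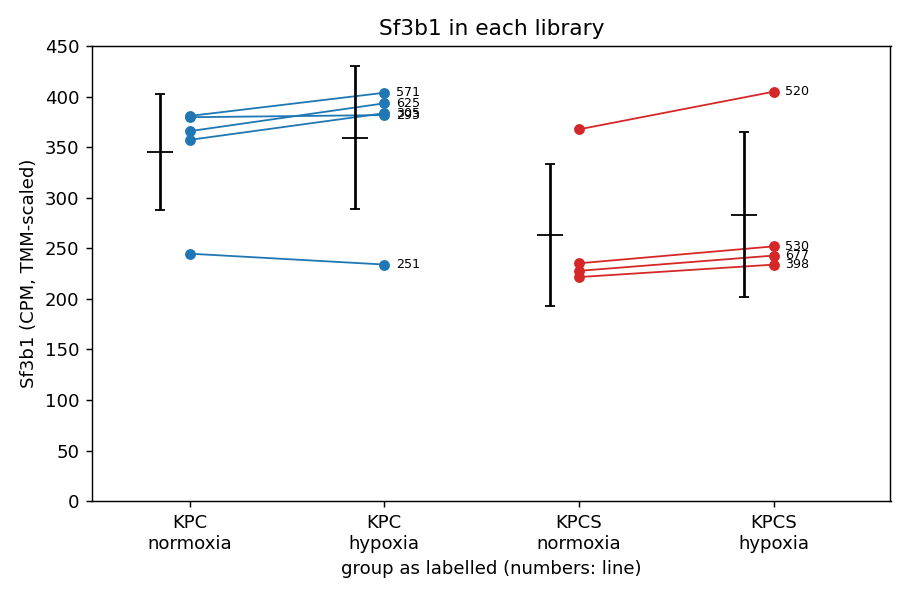
Sf3b1 in CPM for each library, by labelled group, with lines joining the 2 libraries of an organoid line, line numbers beside the points, and black bars for the group mean ± SD (n = 5 for KPC, n = 4 for KPCS). Line KPC251 (244.7 and 233.9) sits among the labelled KPCS lines and line KPCS520 (367.5 and 404.8) among the labelled KPC lines.

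The first comparison asked what 48 h of 1% O2 did to lines labelled KPC. Bnip3, a mitophagy receptor, rose 23.7-fold, from 2.34 ± 1.28 to 55.4 ± 10.6 CPM (n = 5 libraries in each group; log2 fold change 4.56 ± 0.47, adjusted p = 4.16e-05). Car9, the cell-surface carbonic anhydrase IX (chromosome 4, 43506966 to 43513729), rose from 8.55 ± 5.57 to 77.7 ± 37.2 CPM (3.18 ± 0.55, adjusted p = 0.00346). Vegfa, which encodes the main angiogenic growth factor (chromosome 17, 46016993 to 46032369), rose 5.20-fold to 252.2 ± 98.4 CPM (2.38 ± 0.29). P4ha1, a collagen prolyl 4-hydroxylase subunit, had the smallest adjusted p (7.33e-09), with a rise from 27.5 ± 5.16 to 159.2 ± 10.9 CPM. The largest rises by the naming rule were in Slc16a3, the lactate exporter MCT4 (5.38 ± 1.37), and Ak4, a mitochondrial adenylate kinase (4.72 ± 1.17). They were followed by Ankrd37 (4.49 ± 0.42), Ptges, which makes prostaglandin E2 (4.18 ± 0.55), Serpine1 (3.38 ± 0.87), Kctd11 (3.10 ± 0.35) and Sprr1a (2.75 ± 0.43). Ak3l2-ps (4.70) is annotated as a processed pseudogene, and its reads cannot be assigned to it with certainty beside its parent gene. Among falling genes, Rbm3, a cold-inducible RNA-binding protein, dropped from 245.8 ± 25.3 to 90.7 ± 18.1 CPM (-1.44 ± 0.15, adjusted p = 4.21e-05). Slc7a5, the large neutral amino acid transporter, fell (-1.25 ± 0.27), as did the nucleoside carrier Slc29a2 (-1.21), the ribosome assembly factor Rrp12 (-1.14 ± 0.18), the zinc exporter Slc30a1 (-1.02 ± 0.11), the folate carrier Slc19a1 (-0.98), Dagla (-0.97), glutathione reductase Gsr (-0.95 ± 0.16) and Bend3 (-0.93). The signal of Rbm3-ps (-1.79), a processed pseudogene, is uncertain for the same reason as that of Ak3l2-ps.

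Glycolysis genes rose together in KPC lines. Of 23 measured members 19 rose and none fell, or 20 adjusted over the list alone, and 13 rose with the lines labelled KPC251 and KPCS520 left out. Tpi1 (1.54 ± 0.14), Pgk1 (2.06 ± 0.18), Pdk1, a kinase that inhibits pyruvate dehydrogenase (2.13 ± 0.20), and Pgm1 (1.43 ± 0.13) had the smallest p. Ldha, lactate dehydrogenase A, rose from 1124 ± 324 to 2776 ± 471 CPM (1.30 ± 0.19). Slc2a1, the glucose transporter GLUT1 (chromosome 4, 119108711 to 119137983), rose from 171.7 ± 50.9 to 338.3 ± 79.9 CPM (0.98 ± 0.26, adjusted p = 0.0329). The hexokinase Hk2 rose from 48.4 ± 10.1 to 89.8 ± 9.80 CPM (0.89 ± 0.20, adjusted p = 0.0145). Hk1, Pfkfb4 and Pfkm did not pass, nor did Slc2a3 (-0.28). HIF targets outside glycolysis rose in 27 of 34 members, with none falling (30 adjusted over the list alone, and 19 without lines KPC251 and KPCS520), led by P4ha1, the histone demethylase Kdm3a (1.58 ± 0.10), Ero1l (1.58 ± 0.14) and Fam162a (2.24 ± 0.20). Stc2 stood at -0.35 and did not pass. Both lists passed camera with a preset correlation (adjusted p = 9.61e-23 for glycolysis and 3.04e-31 for HIF targets), and they were the only 2 of 26 lists to pass with an estimated correlation (adjusted p = 0.0102 and 3.91e-04). With the line as a paired block 21 glycolysis genes and 31 HIF targets rose and none fell. With that block and an estimated correlation, adjusted p was 0.0768 for glycolysis, which no longer passed, and 0.0319 for HIF targets. Of 17 HIF pathway components 6 rose and 1 fell (8 and 1 adjusted over the list alone, 9 and 1 with the paired block, 2 and 0 without lines KPC251 and KPCS520; camera adjusted p = 0.00642, and adjusted p = 0.0525 with an estimated correlation). These included the HIF prolyl hydroxylases Egln3 (2.16 ± 0.21) and Egln1 (1.25 ± 0.16), the coactivator Crebbp (0.32 ± 0.07) and the chaperone Hsp90ab1 (-0.50 ± 0.12). Hif1a itself (chromosome 12, 73901375 to 73947530), the oxygen-regulated subunit of HIF1, stood at 155.9 ± 48.4 CPM in normoxia and 112.6 ± 36.7 in hypoxia (-0.47 ± 0.23, adjusted p = 0.243). This edgeR p is from the fit without pairing, where spread between lines enters the error, so it is weak evidence of no change. Epas1, which encodes HIF2-alpha, changed by 0.06 ± 0.33 (adjusted p = 0.948) and Sf3b1 by 0.06 ± 0.20 (adjusted p = 0.914). Several nuclear RNAs listed as signs of RNA quality rose in the same libraries, namely Malat1 (2.33 ± 0.30, adjusted p = 3.07e-04), Rn7sk (1.62 ± 0.28) and Neat1 (1.75 ± 0.42), while the list of 20 as a set did not pass (3 rose; adjusted p = 0.210).

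Genes of mitochondrial respiration and of ribosome assembly fell in KPC lines, in the same libraries in which Malat1 rose. A link between these falls and Malat1 was not tested. Oxidative phosphorylation fell in 14 of 28 members (21 adjusted over the list alone, 3 without lines KPC251 and KPCS520), including Ndufv1 (-0.60 ± 0.11), Ndufb8 (-0.55 ± 0.10), Sdhb (-0.38 ± 0.08) and Uqcrc2 (-0.50 ± 0.10). The set passed (adjusted p = 2.40e-13; adjusted p = 0.163 with an estimated correlation). With the line as a paired block 25 members fell, and the set then passed with an estimated correlation too (adjusted p = 0.0319). The TCA cycle fell in 10 of 22 members (15 adjusted over the list alone, 17 with the paired block, 3 without lines KPC251 and KPCS520; adjusted p = 8.27e-09 for the set, adjusted p = 0.0735 with an estimated correlation). In front were Ogdh (-0.58 ± 0.09), Suclg2 (-0.60 ± 0.10), Aco2 (-0.40 ± 0.08) and Idh3g (-0.50 ± 0.10). Its members Pdk2 (0.23), Pdk3 (0.06) and Pdk4 (0.51), kinases that inhibit pyruvate dehydrogenase, did not pass. Ribosome biogenesis factors fell in 17 of 24 members (21 adjusted over the list alone, 22 with the paired block, 2 without lines KPC251 and KPCS520), among them Rrp12, Nolc1 (-0.90 ± 0.18), Nop16 (-0.55 ± 0.12) and Bop1 (-0.54 ± 0.11). The set had adjusted p = 2.11e-14, and adjusted p = 0.225 with an estimated correlation. Myc stood at 0.30 and did not pass. In the spliceosome list of 35 members, 7 fell and 1 rose (18 and 1 adjusted over the list alone, 22 and 3 with the paired block, 2 and 0 without lines KPC251 and KPCS520). Those with the smallest p were Prpf31 (-0.61 ± 0.10), Sf3b4 (-0.57 ± 0.11), Sf3a3 (-0.40 ± 0.09) and Sf3a1 (-0.41 ± 0.10), all down. Tra2a (0.30) rose, and Clk1 (0.38), Clk4 (0.37) and Snrnp70 (0.01) had no call. The set passed with adjusted p = 6.05e-08, and had adjusted p = 0.278 with an estimated correlation.

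Inflammatory NF-kB genes rose in 6 of 20 members in KPC lines (7 adjusted over the list alone, 12 with the paired block, 0 without lines KPC251 and KPCS520), with the chemokines Cxcl1 (1.86 ± 0.35) and Cxcl2, the inhibitor Nfkbia (0.84 ± 0.22) and the cytokine Il1a (2.45 ± 0.66) called and Ccl2 at -0.02. The NF-kB set passed with adjusted p = 4.01e-05 (adjusted p = 0.379 with an estimated correlation). Leukocyte markers moved in the same lines. The NF-kB response was -0.14 in line KPC625 and 0.96 to 1.73 in the other KPC lines, and that of leukocyte markers -0.36 and 0.56 to 1.14. A share of leukocytes as the source was not tested. S phase (0 of 25 members called, adjusted p = 3.42e-06) and mitosis (0 of 25, adjusted p = 0.00642) shifted down as sets. Cytosolic ribosomal proteins (1 of 28, Rpl18 at -0.57 ± 0.14; adjusted p = 3.53e-06) and the NRF2 list (2 of 23, Gsr and Txnrd1 at -0.56 ± 0.15; adjusted p = 0.00716) did too. Cholesterol synthesis shifted up (2 of 22, Msmo1 at 0.64 ± 0.15 and Sc5d at 0.49 ± 0.13; adjusted p = 0.0145). With an estimated correlation these 5 sets had adjusted p = 0.512, 0.815, 0.512, 0.512 and 0.815. Adjusted over the list alone they held 0, 0, 1, 3 and 2 called genes, and with the line as a paired block 15, 10, 24, 10 and 11. Without lines KPC251 and KPCS520 they held 0, 0, 0, 1 and 0. Line KPC625 went the other way in S phase (0.17, other KPC lines -0.80 to -0.40), mitosis (0.20, others -0.69 to -0.20) and the NRF2 list (0.26, others -0.65 to -0.28). Without it cholesterol synthesis did not pass (adjusted p = 0.176), and without KPC305 mitosis did not (adjusted p = 0.0992).

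The remaining lists did not pass in KPC lines. The stress response list (adjusted p = 0.991) held 2 called genes, Ddit3 (1.11 ± 0.23) and Atf3 (1.40 ± 0.29), and the basal list (adjusted p = 0.147) held Sprr1a. Without pairing, no gene was called among interferon genes (adjusted p = 0.118), p53 targets (0.0868), invasion genes (0.597), duct epithelium (0.872) or gastric genes (0.619), and edgeR found unadjusted p under 0.05 for single members such as Ifi44 (-3.01), Polk (0.83), Mmp13 (1.85) and Sox9 (-0.47). With the line as a paired block these 5 lists held 3, 5, 4, 7 and 7 called genes, and the p53 set passed camera (adjusted p = 0.0131), though not with an estimated correlation (adjusted p = 0.610). Line KPC625 stood apart in p53 targets (2.20, other KPC lines 0.10 to 0.26). The stress response list then held 10, the basal list 5 and the RNA quality list 9. Markers of other cell types did not pass either: acinar (7 members, adjusted p = 0.910), fibroblast (5, 0.910), leukocyte (7, 0.0811; Cd68 at 1.01 ± 0.20 was called), endothelial (6, 0.817) and red cell or glial (4, 0.910). With the paired block 3 leukocyte markers and 1 endothelial marker rose and 1 fibroblast marker fell. No endocrine marker had enough counts to be tested. Median, mean and set direction differed in sign for invasion genes (median -0.01, direction up) and for fibroblast markers (median 0.25, mean -0.77).

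In all, edgeR called 1380 genes in KPC lines, 766 up and 614 down, of which 416 and 20 exceeded a log2 fold change of 1, and 4500 genes had an unadjusted p under 0.05. With the organoid line as a paired block the count was 7240, including all 1380 with the same sign. Both fits use the same libraries, so this overlap is not independent support. On simulated counts, false calls with the block made up 8.92% of calls for this contrast. The count was 542 without line KPC251, 491 without KPC293, 492 without KPC305, 300 without both lines in doubt by Sf3b1 and 75 when line KPC625, whose 2 libraries resembled each other least, was left out as well.

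The second comparison asked the same of lines labelled KPCS. P4ha1 rose from 27.6 ± 3.58 to 165.1 ± 13.1 CPM (n = 4 libraries in each group; 2.58 ± 0.13, adjusted p = 3.15e-08). Bnip3 rose 19.9-fold (4.31 ± 0.52), Ankrd37 by 4.37 ± 0.47, Car9 from 4.92 ± 2.62 to 32.8 ± 21.4 CPM (2.73 ± 0.60, adjusted p = 0.0472) and Vegfa from 70.6 ± 17.3 to 211.4 ± 48.9 CPM (1.58 ± 0.32, adjusted p = 0.0283). The other large rises were in Ppp1r3b, which targets protein phosphatase 1 to glycogen, Kctd11 (2.45 ± 0.39), Pdk1 (2.44 ± 0.22), Pfkfb3, which makes the main activator of phosphofructokinase (2.32 ± 0.42), Sprr1a (2.19 ± 0.47) and Egln3 (2.04 ± 0.23). Rbm3 fell from 250.6 ± 40.6 to 103.0 ± 15.3 CPM (-1.28 ± 0.17, adjusted p = 7.21e-04). Gsr (-0.98 ± 0.18), Rrp12 (-0.92 ± 0.20), Snhg5 (-0.82), the aminoacylase Acy1 (-0.79), the RNA-binding proteins Rbmx (-0.74) and Fus (-0.67), the topoisomerase Top3a (-0.67) and the apoptotic nuclease Dffb (-0.65) fell as well, and Rbm3-ps (-1.41) is again uncertain.

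Glycolysis genes rose in 12 of 23 members in KPCS lines and none fell, with 19 called adjusted over the list alone and 21 with the line as a paired block. Pdk1, Tpi1 (1.63 ± 0.15), Pgk1 (1.93 ± 0.20) and Pgm1 (1.33 ± 0.15) led the list, and Ldha rose from 926 ± 179 to 2515 ± 475 CPM (1.44 ± 0.21). Slc2a1 (0.96 ± 0.29, adjusted p = 0.151), Hk2 (0.59 ± 0.22, adjusted p = 0.251) and Slc16a3 (5.19 ± 1.52, adjusted p = 0.135) did not pass, and with the line as a paired block their adjusted p was 6.49e-04, 0.00526 and 0.00166. HIF targets outside glycolysis rose in 14 of 34 members (27 adjusted over the list alone, 29 up and 1 down with the paired block), led by P4ha1, Kdm3a (1.49 ± 0.11), Fam162a (2.01 ± 0.22) and Ankrd37, with Stc2 at -0.41 and no call. Leaving out lines KPC251 and KPCS520 left 7 called glycolysis genes, 9 called HIF targets and 1 called HIF pathway component. Of 17 HIF pathway components 2 rose, Egln3 and Egln1 (1.08 ± 0.18), or 7 up and 1 down adjusted over the list alone, with Crebbp at 0.32 and Cited2 at 0.99. These 3 lists passed camera (adjusted p = 8.68e-28, 5.99e-36 and 1.64e-04) and passed with an estimated correlation (adjusted p = 0.00424, 1.80e-04 and 0.00559). With the paired block and an estimated correlation only HIF targets passed (adjusted p = 0.0384), with 0.0897 for glycolysis and 0.0897 for HIF pathway components, of which 8 rose and 1 fell. In the fit without pairing, Hif1a stood at 156.6 ± 26.1 CPM in normoxia and 115.7 ± 20.9 in hypoxia (-0.44 ± 0.26, adjusted p = 0.509). Epas1 changed by 0.29 ± 0.37 (adjusted p = 0.821) and Sf3b1 by 0.11 ± 0.22 (adjusted p = 0.902) in that fit. Malat1 stood at 1.12 ± 0.32 (adjusted p = 0.123, or 0.00934 with the paired block) and Neat1 at 0.25 ± 0.45 (adjusted p = 0.889).

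Other sets shifted in KPCS lines with few or no called members. Ribosome biogenesis shifted down (1 of 24 called, Rrp12, with Nolc1 at -0.66, Bop1 at -0.41 and Myc at 0.23; 3 adjusted over the list alone and 20 with the paired block; adjusted p = 3.16e-10). S phase (0 of 25, adjusted p = 2.36e-10, Cdt1 at -1.08 and Mcm2 at -0.68), mitosis (0 of 25, 1.08e-05, Cdc20 at -0.85) and the spliceosome (0 of 35, 2.12e-06, Prpf31 at -0.46 and Tra2a at 0.29) shifted down. So did oxidative phosphorylation (0 of 28, 3.66e-05, Cyc1 at -0.54), ribosomal proteins (0 of 28, 1.79e-04, Rpl18 at -0.47), the TCA cycle (0 of 22, 0.00105, Suclg2 at -0.44) and the NRF2 list (1 of 23, Gsr, 0.00949). NF-kB genes shifted up (0 of 20, adjusted p = 4.49e-04, Nfkbia at 1.01 and Cxcl1 at 0.90). Adjusted over the list alone the called members numbered 0, 0, 2, 0, 0, 4, 1 and 2 in these 8 lists, and with the paired block 17, 11, 17, 13, 16, 9, 4 and 5. None of these 9 sets passed with an estimated correlation, where adjusted p ranged from 0.426 to 0.566. The other lists did not pass: RNA quality signs (adjusted p = 0.0547), cholesterol synthesis (0.182), invasion genes (0.182), leukocyte markers (0.231), the basal list (0.302; Sprr1a called), fibroblast markers (0.410), p53 targets (0.477), gastric genes (0.477), interferon genes (0.543), red cell or glial markers (0.543), the stress response (0.676), endothelial markers, duct epithelium (0.777) and acinar markers (0.917). With the paired block the invasion set passed camera (adjusted p = 0.0155), with 3 called genes, but not with an estimated correlation (adjusted p = 0.519).

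In KPCS lines edgeR called 156 genes, 127 up and 29 down (63 and 8 beyond a log2 fold change of 1), with 2560 at an unadjusted p under 0.05. The paired block, fitted to the same libraries, gave 4434, including all 156. The count was 42 without line KPCS677, 43 without KPCS520, 54 without KPCS398 and 64 without KPCS530, and it also moved with KPC lines, which share the estimate of spread, to 98 without KPC293, 102 without KPC305 and 332 without KPC571. It was 29 without lines KPC251 and KPCS520 and 22 without KPC251, KPCS520 and KPC625.

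The responses of the 2 labelled genotypes were then set side by side, with different lines and no shared libraries on either side. Both came from 1 fit that shares the estimate of spread, so the 2 sets of calls are not independent. Without pairing, the calls shared 121 genes up and 22 down, and 0 genes were called in opposite directions. From the numbers called, 5.03 and 0.920 would be expected if the calls were independent. Of the 156 genes called in KPCS, 154 had the same sign in KPC. Across the genes called in KPC, which are not independent replicates, the KPCS log2 fold changes had a slope through the origin of 0.644 on the KPC values, with genes selected for their size in KPC. With the line as a paired block, the calls shared 1742 genes up and 1662 down, and 12 genes were called in opposite directions. Of the 4434 genes called in KPCS with that block, 4296 had the same sign in KPC.

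**Figure D2:**
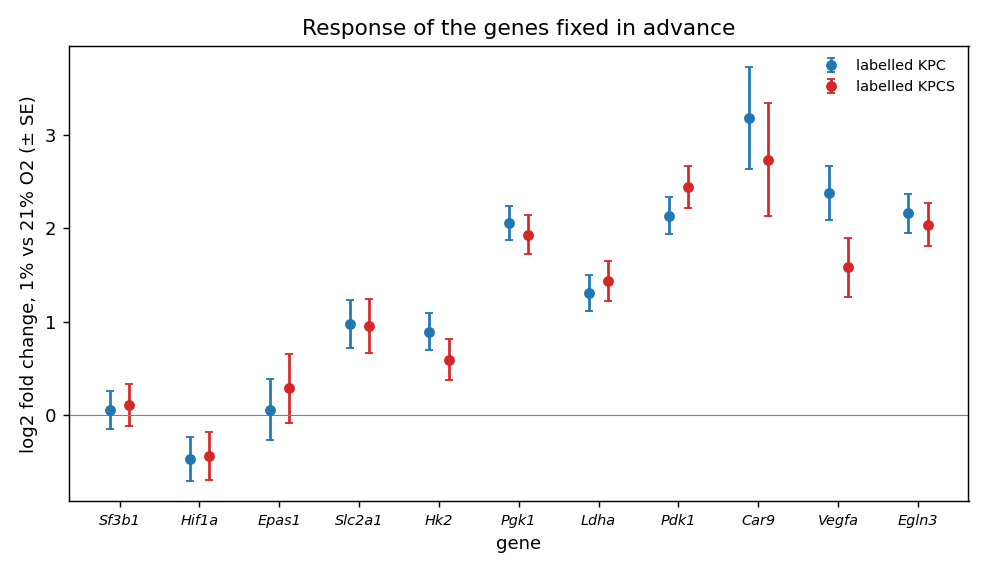
Log2 fold change at 1% against 21% O2 (± SE) of the 11 genes fixed in advance, in lines labelled KPC (n = 5) and KPCS (n = 4). Car9, Vegfa, Egln3, Pdk1, Pgk1 and Ldha lie above 1 in both, while Hif1a (-0.47 and -0.44) lies below 0 in both without a call in the unpaired fit.

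The third comparison was the difference in hypoxia response between KPCS and KPC (KPCS minus KPC). At the level of RNA only, it addresses the question named in the study's title, whether Sf3b1 dosage bears on glycolysis and HIF1-alpha. Gene counts do not measure the HIF1-alpha protein. The directions of this comparison rest on the genotype labels. For the glucose transporter Slc2a1 the difference was -0.02 ± 0.39 on the log2 scale, for Hk2 -0.30 ± 0.30, for Pgk1 -0.13 ± 0.27, for Ldha 0.14 ± 0.28 and for Pdk1 0.30 ± 0.29. For Car9 it was -0.45 ± 0.76, for Vegfa -0.80 ± 0.42 (the largest of these 11 relative to its error), for Egln3 -0.12 ± 0.30, for Hif1a 0.03 ± 0.35, for Epas1 0.23 ± 0.49 and for Sf3b1 0.05 ± 0.30. None of them passed. The naming rule, which leaves out predicted genes and genes with a mean under 5 CPM, gave the 5 remaining genes with the smallest p because fewer than 5 passed. The smallest adjusted p of all was 0.407, for the predicted gene Gm29237. The 5 were the kinase Dmpk (-0.96 ± 0.23), the ubiquitin ligase Trim39 (-0.65), Snrnp48 of the minor spliceosome (-0.54), Gtpbp2 (-0.65) and the zinc exporter Slc30a1 (0.56 ± 0.16), each with adjusted p = 1.00.

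As sets, 4 lists had a higher response in lines labelled KPCS by camera. The first was oxidative phosphorylation (28 of 28 members positive, median 0.18, adjusted p = 2.04e-07, Ndufb8 at 0.36 ± 0.15 and Sdhb at 0.23 ± 0.11). The others were the TCA cycle (21 of 22 positive, adjusted p = 3.32e-05, Sucla2 at 0.26 ± 0.11 and Pdk2 at -0.12) and ribosome biogenesis (21 of 24, adjusted p = 0.00116, Utp20 at 0.39 ± 0.25, with Nop56 at -0.09, Noc2l at -0.08 and Myc at -0.07). Interferon genes were the last (25 of 27, adjusted p = 0.00831, Ifi44 at 3.46 ± 1.43, with Stat2 at -0.36 and Mx1 at -1.27). The interferon response was -2.65 in line KPC625, -0.35 to 0.44 in the other KPC lines and 0.03 to 0.22 in KPCS lines, a difference of 0.53 per line (exact p = 0.619). HIF targets outside glycolysis had a lower response (27 of 34 negative, median -0.20, adjusted p = 0.0395), with Vegfa and Ero1l (-0.32 ± 0.20) in front and Ak4 (1.07), Plod1 (0.29), Serpine1 (0.23), Angptl4 (0.09), Bnip3l (0.08), P4ha1 (0.05) and Bhlhe40 (0.01) on the other side. No list had a called member, over all genes or adjusted over the list alone, and no list passed with an estimated correlation (adjusted p = 0.923 for each of these 5) or with fry (0.990). Glycolysis did not pass (median -0.05, adjusted p = 0.679), and the other 20 lists had adjusted p from 0.210 to 0.958. With the line as a paired block, ribosomal proteins passed as well (adjusted p = 0.0337, 0.225 without the block). With 1 line left out, oxidative phosphorylation, the TCA cycle and ribosome biogenesis passed each time. HIF targets did not pass without KPC293 (adjusted p = 0.206), KPC571 (0.0885), KPC625 (0.0777), KPCS398 (0.260) or KPCS677 (0.182). Without KPC625 interferon genes did not pass (adjusted p = 0.999) and NF-kB genes did, with a lower response in KPCS (adjusted p = 0.00922). The number of lists that passed was 8 without line KPC305 and 8 without line KPCS530.

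Response per line gave each animal 1 value. The mean glycolysis response was 1.54 ± 0.21 (log2 CPM, SD, n = 5) in lines labelled KPC and 1.44 ± 0.19 (n = 4) in lines labelled KPCS, a difference of -0.10 (exact permutation test, two-sided, p = 0.492). For HIF targets outside glycolysis it was 1.96 ± 0.25 and 1.75 ± 0.23, a difference of -0.22 (exact p = 0.238). Both differences were smaller than the spread between lines, and with the median over each list in place of the mean they were 0.02 (exact p = 0.905) and -0.27 (exact p = 0.0159). Over all 26 lists, oxidative phosphorylation had the smallest p: -0.36 ± 0.04 in KPC and -0.18 ± 0.03 in KPCS, with every KPCS line above every KPC line (exact p = 0.0159, the smallest that the design allows; adjusted over 26 lists 0.413). This rests on the labels of the lines in doubt, KPC251 (-0.35) and KPCS520 (-0.22), and would be lost if both were wrong. Relative to ribosomal proteins, a check chosen afterwards, the difference was 0.10 and the lines overlapped (exact p = 0.365). Of the signs of RNA composition, Malat1, 1 member picked from the RNA quality list, rose by 2.33 in KPC and 1.12 in KPCS. The gene class TEC (to be experimentally tested), chosen after its values were seen, stood at 0.50 and -0.06 relative to protein-coding genes. The RNA quality list as a whole did not pass between genotypes (0.40 ± 0.17 in KPC and 0.26 ± 0.14 in KPCS, exact p = 0.238). By p, the TCA cycle came next among the lists after oxidative phosphorylation, at -0.28 ± 0.09 and -0.10 ± 0.05 (exact p = 0.0317, adjusted 0.413). At normoxia the mean level of the oxidative phosphorylation genes was 0.23 lower in KPCS on the log2 scale (difference -0.23, exact p = 0.0476), and at hypoxia the difference was -0.05 (exact p = 0.524).

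**Figure D3:**
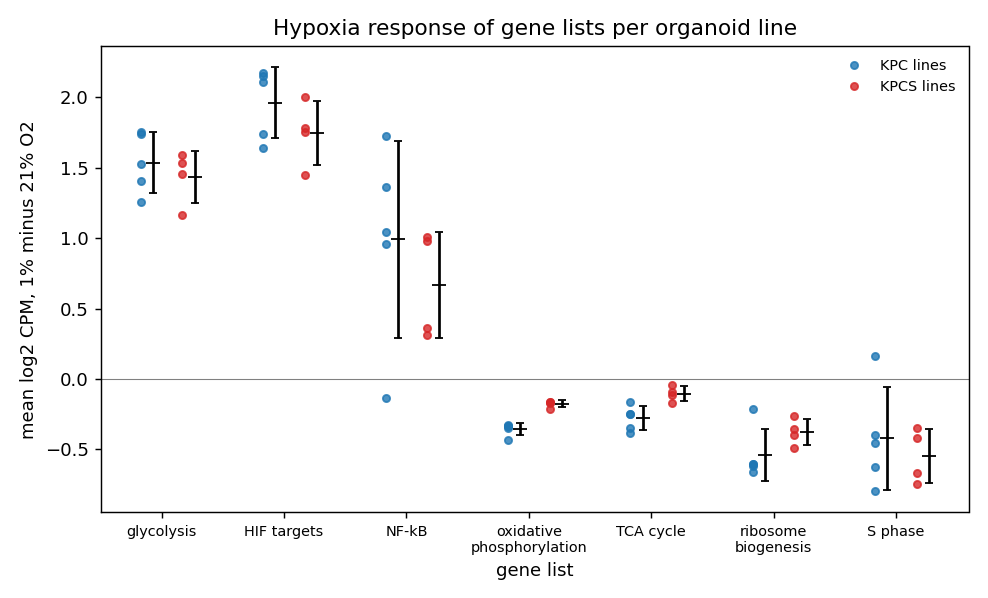
Response of 7 gene lists to 1% O2 in each organoid line, as the mean over the list of log2 CPM at 1% minus 21% O2, with black bars for the mean ± SD of the lines labelled KPC (n = 5) and KPCS (n = 4). Glycolysis (means 1.54 and 1.44) overlaps between genotypes, while every oxidative phosphorylation value of KPCS lies above those of KPC.

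No gene passed edgeR for a difference in response (0 of 19356). An unadjusted p under 0.05 was reached by 521 genes, 2.69% where 5% would be expected by chance. That fit leaves out the pairing of libraries, so spread between lines enters its errors, and its 0 is weak evidence of equal responses. DESeq2 called 2 predicted genes (Gm44986 and Gm29237), limma-voom with the line as a random effect called 67 (1 up and 66 down), and edgeR with the paired block called 1, 2900005J15Rik (-3.45), a name chosen after its value was seen. On counts simulated with no line differences and the unpaired dispersion, the unpaired fit recovered 45 of 100 genes altered 4-fold in response. The paired block recovered 75 of 100 on other counts, simulated with line means and the dispersion of the block. These 2 figures come from different counts, so their gap does not measure what pairing gains. In either setting, differences of that size in single genes could be missed.

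The fourth comparison set lines labelled KPCS against lines labelled KPC at normoxia. Beside Sf3b1, the 5 genes with the smallest p by the naming rule were the adhesion molecule Mpzl2 (-0.67 ± 0.14), the glycosyltransferase Galnt11 (0.52), the mitochondrial carrier Slc25a42 (0.70), Reep6 (-0.74) and Trim39 (0.52), each with adjusted p = 0.816. Genes fixed in advance stood at 0.12 ± 0.27 for Slc2a1, -0.05 ± 0.21 for Hk2, -0.13 ± 0.19 for Pgk1, -0.28 ± 0.20 for Ldha, -0.46 ± 0.20 for Pdk1, -0.80 ± 0.55 for Car9 and 0.54 ± 0.29 for Vegfa. They stood at -0.13 ± 0.21 for Egln3, 0.01 ± 0.25 for Hif1a and -0.62 ± 0.35 for Epas1, none with a call. Oxidative phosphorylation genes were lower as a set (28 of 28 negative, median -0.25, adjusted p = 5.12e-13), with Sdhb (-0.29 ± 0.08), Sdhc (-0.21 ± 0.07), Atp5o (-0.33 ± 0.11) and Cox5a (-0.38 ± 0.14) in front. The TCA cycle (adjusted p = 0.00109; Suclg1 at -0.24 ± 0.06, the only member of this list called over the list alone, Pdk2 at 0.54 and Pdk4 at 0.08) and ribosomal proteins (0.00109; Rps27 at -0.37 and Rps18 at 0.17) were lower as well. The spliceosome was lower (adjusted p = 0.00813; Sf3b4 at -0.31, Snrpb2 at -0.21, and on the other side Clk1 at 0.37, Clk4 at 0.34, Snrnp70 at 0.15, Sf3b3 at 0.14, Rbm25 at 0.07, Tra2a at 0.03 and Snrnp200 at 0.00). The same held for ribosome biogenesis (adjusted p = 0.0133; Nop16 at -0.22 and Wdr12 at 0.05, Nop56 at 0.03), mitosis (0.0334; Bub1b at -0.31 and Cenpf at 0.06, Aurka at 0.01) and interferon genes (0.0334; Ifi44 at -2.57 and Gbp2 at 0.17, Stat2 at 0.00). Both Ifi44 and Xaf1 rested on line KPC625, since without it Ifi44 stood at 0.55 and Xaf1 at 0.04 (-1.53 with it). The p53 targets (adjusted p = 0.0133; Tnfrsf10b at 0.36, Sesn1 at -0.58, Perp at -0.42, Pmaip1 at -0.07 and Fas at -0.55) were higher. Without line KPC625, which stood apart in this list, it did not pass (adjusted p = 0.163), nor did interferon genes (adjusted p = 0.195). So were invasion genes (adjusted p = 0.0334; Tnc at 1.36, and against it Snai2 at -2.56, Tgfbi at -2.09, Zeb2 at -1.95, Mmp7 at -1.74, Itgb3 at -1.70 and Mmp13 at -0.58), with median 0.18 and mean -0.14. With an estimated correlation oxidative phosphorylation had adjusted p = 0.776 and the other 8 had 0.859. The RNA quality list did not pass, but Malat1 was called over the list alone, as was Xist, and over all genes neither was. Malat1 stood at 301.6 ± 123.1 CPM in KPC and 635.8 ± 193.4 CPM in KPCS (1.08 ± 0.30, adjusted p = 0.816). The other 17 lists had adjusted p from 0.0829 to 0.963, glycolysis 0.163 and HIF targets 0.963. Only oxidative phosphorylation passed whichever line was left out. Glycolysis passed, lower in KPCS, without KPC625 (adjusted p = 0.0166) and without KPCS398 (adjusted p = 0.00296).

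At normoxia edgeR called 0 of 19356 genes (1108 at an unadjusted p under 0.05), and DESeq2 called 22. The counts were 4 without lines KPC251 and KPCS520 (Sf3b1, Gm3375, Gm26782 and Ppp1r3e) and 4 without KPC251, KPCS520 and KPC625 (Muc5b in place of Gm3375), genes named after their values were seen. The number of lists that passed, 9, was 5 without line KPC251, 4 without KPC571, 5 without KPCS398, 4 without KPCS520, 3 without KPCS677 and 4 without KPC251 and KPCS520.

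The fifth comparison set the labelled genotypes against each other at hypoxia. The 5 genes with the smallest p by the naming rule were Vcl, the adhesion protein vinculin (0.65 ± 0.14), Dpy19l1 (0.58) and Xist, the RNA that silences an X chromosome (12.14 ± 2.96). The other two were Id1, an inhibitor of differentiation (-1.35 ± 0.34) and Pop4, a subunit of RNase P (1.10 ± 0.29). Each of the 5 had adjusted p = 0.992. Xist stood at 806.1 and 1302 CPM in the lines labelled KPCS530 and KPCS677 and below 1 CPM in every other line, so it followed the sex of the animals. Among the fixed genes, Car9 was at -1.24 ± 0.55, Hk2 at -0.35 ± 0.21, Pgk1 at -0.26 ± 0.19, Vegfa at -0.25 ± 0.30 and Egln3 at -0.25 ± 0.21. Pdk1 was at -0.15 ± 0.20, Ldha at -0.14 ± 0.20, Epas1 at -0.39 ± 0.35, Hif1a at 0.04 ± 0.25 and Slc2a1 at 0.10 ± 0.27. As sets, mitosis (25 of 25 negative, adjusted p = 1.54e-05; Ttk at -0.32) and S phase (24 of 25, 1.07e-04; Pold1 at -0.43 and Ccne2 at 0.05) were lower in KPCS. Cholesterol synthesis was lower (19 of 22, adjusted p = 4.11e-04; Fdps at -0.46, with Dhcr24 at 0.08, Hmgcs1 at 0.06 and Idi1 at 0.04). HIF targets outside glycolysis were lower (28 of 34, adjusted p = 0.00652; Ero1l at -0.35 ± 0.14, Higd1a at -0.32 ± 0.14 with Plod1 at 0.50, Stc2 at 0.31, Angptl4 at 0.25, Plod2 at 0.16, Bhlhe40 at 0.06 and P4ha1 at 0.05). So was glycolysis (19 of 23, adjusted p = 0.0197; Pfkp at -0.61 ± 0.36 with Pfkfb4 at 0.17, Aldoc at 0.13, Pfkm at 0.12 and Slc2a1 as above). NF-kB genes were lower too (15 of 20, adjusted p = 0.0398; Il1a at -2.17 ± 0.71 with Ccl2 at 0.69, Icam1 at 0.39, Nfkb2 at 0.17, Relb at 0.16 and Tnfaip3 at 0.16). Leukocyte markers leaned the same way without passing (5 of 7 negative, median -0.64, adjusted p = 0.143). Invasion genes were higher (15 of 20 positive, adjusted p = 6.94e-04; Tnc at 1.82 ± 0.85, Cd44 at 0.52 ± 0.26 with Tgfbi at -2.67, Mmp7 at -2.37, Snai2 at -2.13, Mmp13 at -0.77 and Lamc2 at -0.02). None of the 7 had a called member, and with an estimated correlation each had adjusted p = 0.887. The other 19 lists had adjusted p from 0.0882 upwards. Only invasion genes passed whichever line was left out. Glycolysis did not pass without KPC293, KPC305, KPCS520 or KPCS677 (adjusted p from 0.0530 to 0.297), nor HIF targets without KPC293, KPC305, KPCS530 or KPCS677 (0.0530 to 0.145).

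At hypoxia edgeR called 0 of 19356 genes (684 at an unadjusted p under 0.05), and DESeq2 called 5: Xist, 1110019D14Rik, Mgam2-ps, Igsf23 and Vcl. The count was 1 without line KPC625 (Dpy19l1), 1 without KPCS520 (Pop4), 4 without KPC251 and KPCS520 (Sf3b1, Pop4, Gm26782 and Ppp1r3e) and 1 without KPC251, KPCS520 and KPC625 (Ppp1r3e). The number of lists that passed, 7, was 15 without line KPC571 and 2 without line KPCS677.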

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

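The exchange test for Sf3b1, the 3 tests on line KPC625, the test on the libraries in doubt and the 4 gene classes were chosen only after the values they concern had been seen. A far sample was looked for in 102 sets of values with Dixon's test. It was found in 14, where 5.1 would be expected by chance at 1 in 20.

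Sf3b1 was far from its group in both libraries of the line labelled KPC251 (244.7 and 233.9 CPM) and of the line labelled KPCS520 (367.5 and 404.8 CPM). An exchange of these 2 lines between the genotypes, at any step from animal to label, needs each value near the other genotype's mean, and 4 of 4 values were within 15% of it. A loss or gain of the chromosome region was excluded as far as expression of 81 neighbouring genes within 10 Mb can show: their median log2 ratio was -0.065 in line KPC251 (95% interval -0.13 to 0.033, Sf3b1 at -0.67) and 0.039 in line KPCS520 (-0.034 to 0.066, Sf3b1 at 0.71). The hypoxia response ran with the labels, in oxidative phosphorylation (-0.35 in KPC251 and -0.22 in KPCS520) and in the gene class TEC (0.65 and -0.05), but both measures were chosen for parting the labelled groups. Wrong genotype labels for KPC251 and KPCS520 remain open, and so does a biological cause limited to Sf3b1, which is a hypothesis that was not tested. Lower expression of an intact allele, for example, could concern only KPC251. In KPCS520, Sf3b1 stood at 161% and 167% of the other KPCS lines. Genotyping of the RNA or DNA reads would decide between wrong labels and a biological cause.

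In line KPC625 the normoxia and hypoxia libraries differed far more than those of any other line. Their correlation was 0.296 (others in KPC from 0.767). The list responses of KPC625 were far from the other KPC lines for interferon genes (-2.65, others -0.35 to 0.44), ribosome biogenesis (-0.22, others -0.67 to -0.60), p53 targets (2.20, others 0.10 to 0.26) and invasion genes (-0.89, others 0.45 to 0.65), as was Epas1 at normoxia (51.98 CPM, others 20.3 to 28.4).

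The sum of 4 Y-linked genes in KPC625 was 9.67 CPM at normoxia and 185.5 CPM at hypoxia, 5.22%, a mean log2 difference of 4.36, while in the other Y-bearing lines the largest was 0.446, so the change of oxygen was excluded as the cause. Exchange with another line of the series was also excluded, since the highest correlation of the normoxia library with another line was 0.485. That was with the normoxia library of KPCS520, and it was above the 0.296 of KPC625's own pair. It was below the lowest own pair of the other lines (0.767 in KPC305). A source outside the series could not be tested. Whether cells like those of the hypoxia library made up a minor share of the normoxia library was undecided, with 9 genes below the bound where 10 were set as the limit. Each of the other 8 lines had 0 such genes, and Eda2r had 64.5 CPM at hypoxia and 1 count at normoxia, which speaks against a shared minor population. That test was rewritten after its earlier form had selected no gene. Loss of the Y chromosome is a biological hypothesis that was not tested. It would have to cover most of the normoxia culture, since 5.22% of the Y-linked signal remained. By itself it does not address genes off the Y chromosome, such as Eda2r on the X chromosome.

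Non-coding gene classes rose more at 1% O2 in lines labelled KPC than in lines labelled KPCS. The 532 genes of the class TEC (to be experimentally tested) changed by 0.50 ± 0.22 (SD, n = 5) relative to protein-coding genes in KPC and by -0.06 ± 0.06 (n = 4) in KPCS, a difference of -0.558. In KPCS lincRNA changed by 0.08 ± 0.06, antisense genes by -0.08 ± 0.06 and processed transcripts by 0.02 ± 0.03, with differences of -0.28, -0.50 and -0.34. The classes were chosen after their values were seen, so no p is given for them.

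For the non-coding classes, low expression did not account for the whole TEC difference, which was -0.438 against protein-coding genes of like level. It may account for part, since matching on level lowered the KPC rise from 0.50 to 0.30. The lines then barely parted (lowest KPC line 0.030, highest KPCS line 0.013). The libraries in doubt were excluded as the cause, since the TEC difference was -0.579 without lines KPC251, KPCS520 and KPC625. Genomic DNA was undecided: the summed receptor genes not expected in these cells differed by -0.175 (exact p = 0.333). A differing share of unprocessed or nuclear RNA stays open, since the value used for it (-0.558) is the pattern itself. The level of the class was 0.39 higher in KPCS at normoxia, where the lines parted narrowly. At hypoxia it was 0.18 lower in KPCS and the lines overlapped, so the levels do not place the difference in the KPC hypoxia libraries. A difference in transcription linked to genotype stays an untested hypothesis.

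Other far samples were the total counts of KPC normoxia line KPC571 (33.2 M counts, others 47.3 to 52.2), the oxidative phosphorylation response of KPC571 (-0.43, others -0.35 to -0.33) and of KPCS520 (-0.22, others -0.17 to -0.16), and the acinar response of KPC305 (0.21, others -0.19 to -0.17). No cause was tested for these.

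Differences between the labelled genotypes were found in the per-line response of oxidative phosphorylation (0.18) and the TCA cycle (0.17; adjusted p over the lists 0.413 for both), and by camera on the interaction for HIF targets outside glycolysis (adjusted p = 0.0395), oxidative phosphorylation (2.04e-07), the TCA cycle (3.32e-05), interferon genes (0.00831) and ribosome biogenesis (0.00116). These 5 lists had adjusted p = 0.923 with an estimated correlation and 0.990 with fry. For oxidative phosphorylation the difference was 0.18 with DESeq2 size factors (exact p = 0.0159), 0.10 relative to ribosomal proteins (exact p = 0.365, with overlap of the lines) and 0.20 without lines KPC251, KPCS520 and KPC625 (exact p = 0.1, the smallest possible). These 3 checks were chosen after the difference was seen.

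Splits of the same libraries into other groups of the same size show how often such counts arise without the labels. For hypoxia in KPC, 1 of 100 splits, the real one, reached 1380 genes, and the highest other had 1031. In most of these splits both libraries of some line fell in 1 group, so they do not test oxygen within lines. Among the 13 splits that part all 5 pairs, only the real one reached 1380 and the highest other had 0. That number of splits is too small to exclude chance. For hypoxia in KPCS, 2 of 35 splits reached 156, and the highest other had 342, so the count of genes alone does not exclude chance, although among the 8 splits that part all 4 pairs the highest other had 0. For the interaction 100 of 100 splits reached the real 0 genes (highest other 0), for genotype at normoxia 100 of 100 (highest other 443) and for genotype at hypoxia 100 of 100 (highest other 610). Any split reaches a count of 0, so these 3 say nothing on chance. For lists, 34 of 100 splits reached the real 13 for hypoxia in KPC (highest other 17), 8 of 35 the real 12 in KPCS (13), 74 of 100 the real 5 for the interaction (11), 48 of 100 the real 9 at normoxia (18) and 66 of 100 the real 7 at hypoxia (14). Chance cannot be excluded for any count of lists, so the list shifts of the interaction and of genotype may be due to structure among the samples.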

How the results depend on the processing

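Leaving out lines KPC251 and KPCS520, or these with KPC625, and the paired block without KPC625 were chosen only after the values were seen. Over 273 results of 155 named genes, 4959 alternatives were computed: 4411 kept direction and call, 299 were weaker, 210 were stronger and 39 were reversed. Where no cause is given, the cause was not tested.

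The count of genes called for hypoxia in KPC (1380) kept within 1.5-fold with the size factors of DESeq2 and the filters. It was 7240 with the paired block, 9152 with the block and without line KPC625, 7401 with limma-voom, which also pairs, and 2383 with DESeq2. It was 579 with only the 2 groups compared, 300 without lines KPC251 and KPCS520, and 75 without KPC251, KPCS520 and KPC625, where fewer samples enter. Leaving out 1 line gave 491 (KPC293) to 1673 (KPCS530), with 542 without KPC251 and 492 without KPC305.

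The count for hypoxia in KPCS (156) was 4434 with the paired block, 7169 with the block without line KPC625, 4540 with limma-voom, 637 with DESeq2, 69 with no filter, 68 with only the 2 groups, 29 without lines KPC251 and KPCS520 and 22 without KPC251, KPCS520 and KPC625. Leaving out 1 line gave 42 (KPCS677) to 332 (KPC571), with 98 without KPC293, 102 without KPC305, 54 without KPCS398, 43 without KPCS520 and 64 without KPCS530.

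For the interaction the count of 0 was 1 with the paired block, 2 with DESeq2, 67 with limma-voom and 5 with the block without line KPC625 (Firre at -0.91, A530020G20Rik at -1.45, 2900005J15Rik at -3.42, the uncertain Pisd-ps1 at -1.07 and a gene without a symbol). Leaving out 1 line gave 0 each time. For genotype at normoxia the 0 was 22 with DESeq2, 4 without lines KPC251 and KPCS520 and 4 without KPC251, KPCS520 and KPC625. At hypoxia the 0 was 5 with DESeq2, 4 without KPC251 and KPCS520, 1 without KPC251, KPCS520 and KPC625, and 0 to 1 when 1 line was left out, with 1 without KPC625 and 1 without KPCS520.

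Sf3b1 in KPCS against KPC (-0.39 at normoxia, -0.34 at hypoxia) ranged from -0.60 (without KPCS520) to -0.31 (without KPCS398) and from -0.56 to -0.26 over lines left out. With edgeR it was -0.70 and -0.68 without KPC251 and KPCS520 (adjusted p = 0.00926 and 0.0121). Without KPC251, KPCS520 and KPC625 it was -0.71 at normoxia (adjusted p = 0.0423) and -0.68 at hypoxia, where it was not called (adjusted p = 0.0565). The cause lies in the choice of lines, which was made on Sf3b1.

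The difference in glycolysis response (-0.10) reversed with the median over the list (0.0157) and ranged from -0.17 (without KPC251) to -0.01 (without KPCS398) over lines left out. That of HIF targets (-0.22) was stronger with the median (-0.27, exact p = 0.0159) and ranged from -0.30 to -0.12.

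Of the lists moved, the 13 for hypoxia in KPC were 2 with an estimated correlation and 8 with fry (12 to 15 over lines left out). The 12 in KPCS were 3 and 3 (11 to 14), and the 5 of the interaction 0 and 0 (4 to 8, with 8 without KPC305 and 8 without KPCS530). The 9 at normoxia were 0 and 0 (3 to 11, with 5 without KPC251, 4 without KPC571, 5 without KPCS398, 4 without KPCS520, 3 without KPCS677 and 4 without KPC251 and KPCS520), and the 7 at hypoxia were 0 and 0 (2 without KPCS677 to 15 without KPC571).

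In the interaction, Hif1a (0.03) was -0.0208 with the stricter filter, -0.12 without KPC251 and KPCS520, -0.0540 without KPC251, KPCS520 and KPC625, and -0.18 to 0.23 over lines left out. Epas1 (0.23) was -0.13 without KPC251, KPCS520 and KPC625, -0.00937 with the paired block without KPC625, and -0.0174 to 0.34 over lines left out. Slc2a1 (-0.02) was 0.0798 without KPC251, KPCS520 and KPC625, 0.10 with the paired block without KPC625, and -0.10 to 0.0915 over lines left out, and Egln3 (-0.12) was -0.28 to 0.10. For hypoxia in KPC, Epas1 (0.06) was -0.0483 to 0.30 over lines left out.

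At normoxia, Hif1a (0.01) was -0.12 without KPC251, KPCS520 and KPC625 and -0.14 to 0.18 over lines left out. Slc2a1 (0.12) was -0.0510 and -0.13 to 0.26, and Hk2 (-0.05) was 0.16 without KPC251 and KPCS520, 0.10 without KPC251, KPCS520 and KPC625 and -0.22 to 0.11. Ifi44 (-2.57) was 0.33 without KPC251, KPCS520 and KPC625 and -2.87 to 0.55 over lines left out, and Xaf1 (-1.53) was -1.87 to 0.0436, both reversed by leaving out line KPC625 alone, so this line decides both values. Snai2 (-2.56) was 0.14 with limma-voom. At hypoxia, Hif1a (0.04) was -0.0452 without KPC251 and KPCS520, -0.18 without KPC251, KPCS520 and KPC625 and -0.0591 to 0.24, and Slc2a1 (0.10) was -0.13 to 0.22.

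The smallest library held 33.2 M counts, and no test of depth was run. The common biological coefficient of variation was 49.7% between libraries of a group. It was 17.0% with the paired block, which removes the differences between lines.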

Other observations

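Line KPC571 differed from the other lines in basal keratins, genes chosen after their values were seen. Krt14 stood at 1484 CPM in its normoxia library and 2048 in its hypoxia library, Krt5 at 4289 and 4627, Trp63 at 95.1 and 98.8, Krt6a at 274 and 717, and Krt16 at 54.1 and 296. No cause was tested.

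In the lines labelled KPC, Malat1 ranged from 165 to 480 CPM at normoxia and from 1282 to 2025 at hypoxia, without overlap, while the lines labelled KPCS ranged from 475 to 915 and from 781 to 1986. At normoxia the class TEC was 0.39 higher in KPCS on the log2 scale, and at hypoxia the difference was -0.18. This class was chosen after its values were seen.

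The lines labelled KPCS530 and KPCS677 carried Xist (888.7 and 806.1 CPM, 1401 and 1302 CPM at normoxia and hypoxia) and lacked Y-linked genes, and all other lines had Y-linked genes, so sex was not balanced between the genotypes.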
